A study of Homo sapiens with 72 samples.

How the data were processed

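Total RNA was isolated with TRIzol from cells held overnight without serum and then given TGF-β (5 ng/mL) or SB431542 (10 µM), with ligand buffer and DMSO named as the vehicles, per the labels' protocols. Libraries were prepared and sequenced on the Illumina platform at a sequencing company. The submitters' processing notes name FastQC, cutadapt 2.10, HISAT2 2.2.0, StringTie 1.3.6 and the build GRCh38; parameters, annotation release, strand setting and filters are not given in the sources used here. The authors deposited TPM values for 96411 lncRNA genes, all with NONCODE gene identifiers, in 72 columns, each matched to its sample by the sample's label. In every library these TPM were scaled over the lncRNA genes alone, so a change in a few abundant lncRNA genes shifts all others. Protein-coding genes were not analysed here. TPM keeps no depth, so no counting error, interval or detection limit could be given, and low values are less certain by an unknown amount. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads may be shared between near-identical genes.

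Groups were taken from the sample labels (3 lines, 2 agents, 4 times, 3 replicates). The series' design text speaks of 36 samples, and 72 are listed. It calls the triplicates biological; where they were not separate cultures, p-values measure only the spread between these samples. No column was identical to another. The labels disagree on the time of the earliest SB samples (0 h in the titles, 0.5 h in the treatment field), and the titles were followed for grouping.

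Genes of at least 0.5 TPM in at least 3 libraries of a fit were tested on log2(TPM + 0.5) with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in R 4.3.3. The table was read with data.table (version 1.17.8). Within a line all 24 libraries (8 groups) entered the fit; comparisons between 2 lines and interactions used their 48 libraries. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in a fit, and a gene was called at an adjusted p under 0.05. The 22 contrasts, the test, the rule for naming genes and the following other settings were fixed before the data were examined: a pseudocount of 1 or 0.1, no filter, a mean of at least 1 TPM, median-of-ratios scaling, the replicate number as a block, the compared groups alone, and leaving out each library. A further 3 settings were added after the data were seen. In the first, the 27 genes with a mean of at least 100 TPM and a within-group SD over 1 (log2) in any line were left out and the libraries rescaled to a common total. In the second, the 10 genes of highest mean TPM were left out of the scaling total and still tested. In the last, the log2 values were quantile normalized over the libraries of a fit. Genes shared by the lines were counted per direction and set beside the number expected for independent lists; no library is shared between lines.

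The naming rule takes called genes whose 3 libraries in one group all lie beyond the 3 in the other, ranked by absolute log2 change, and asks for a gene symbol. The files do not pair the identifiers with symbols, and 0 of the identifiers matched the RefSeq gene table or the GENCODE annotations used. The identifier stood in for the symbol, and only 2 identifiers per direction are printed, also where a count is 5 or fewer, the first by rank among genes called with the same sign in all 3 lines. Positions, transcripts and names of the genes were not used here. For the same reason the 25 gene lists fixed beforehand, their set tests and the level of HRAS in the transformed line were not analysed here. Every feature is an lncRNA gene, so the planned counts of genes and of lncRNAs are one and the same.

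The fit was tested on simulated tables of each line in which the 24 h TGF-β group had 200 changed genes and residuals were shuffled. For the M1 comparison (20345 genes tested) 77.3% of genes changed by 2 on the log2 scale, 31.3% of those changed by 1 and 4.48% of those changed by 0.5 were called, with 4 false calls. For M2 (16106 genes) the shares were 78.8%, 20.9% and 1.49%, with 2 false calls, and for MDA-MB-231 (16103 genes) 84.8%, 31.3% and 0%, with 4 false calls. With no gene changed there was 1 call in M1 and 0 in M2 and in MDA-MB-231. Small changes were therefore mostly missed in tables with so few changed genes, which were picked at a mean of at least 1 TPM. The adjusted p is less strict where more genes change. In M1 at 24 h of TGF-β, 302 of 544 higher and 1234 of 2917 lower calls had a log2 change of at least 1 in size. Residuals were shuffled gene by gene, which removes shifts common to a whole library, so false calls from scaling were not measured. The recovery required at a log2 change of 2 was lowered after a first run fell short of it, with the fit unchanged.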

Results

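The levels of long non-coding RNA (lncRNA) genes were measured by sequencing total RNA from 3 human breast cell lines. MCF10A-M1 (M1) is a non-malignant mammary epithelial line, MCF10A-M2 (M2) is its derivative transformed with HA-Ras, and MDA-MB-231 is a triple-negative breast cancer line. Each line was given either TGF-β at 5 ng/mL, the ligand of the TGF-β receptors, or SB431542 (SB) at 10 µM, an inhibitor of the kinase of the type I TGF-β receptor. Libraries were made at 0, 2, 8 and 24 h, with 3 biological replicates in each of the 24 groups, 72 libraries in all. The TGF-β samples at 0 h were the non-stimulated controls. The first SB samples carry the time 0 h in their titles and 0.5 h in their treatment labels, and are called the earliest SB samples here.

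The table held 96411 lncRNA genes of the NONCODE catalogue in TPM, a measure of transcript share corrected for length, scaled so that these genes alone make up the whole of every library. TPM keeps no read depth, so the depth of each library is unknown. The number of lncRNA genes at 0.5 TPM or more ranged from 8458 to 16748 per library, with a median of 13174. A single gene took 21.1% to 39.6% of the TPM of a library, and the 10 most abundant genes together took 46.7% to 78.4%. Replicates of a group correlated with r from 0.93 to 0.966 across genes on the log2 scale; genes are not independent replicates. In M2 the number of lncRNA genes at 0.5 TPM or more was 13571 ± 910 (SD, n = 3) in the non-stimulated controls and 9080 ± 921 (n = 3) after 24 h of TGF-β. It was 13123 ± 1020 (n = 3) in the earliest SB samples of M2 and 9310 ± 42.9 (n = 3) after 24 h of SB. In both arms of M2 every library at 24 h lay below every library at the start.

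**Figure D1:**
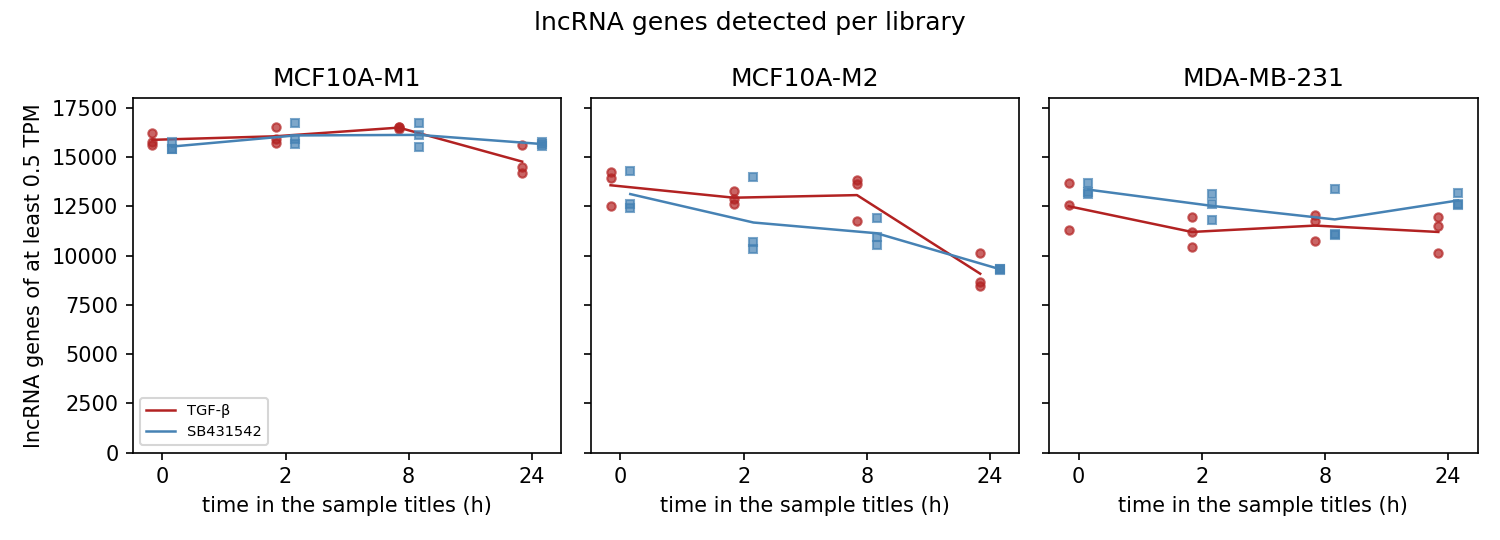
Number of lncRNA genes of at least 0.5 TPM in each of the 72 libraries (points; circles TGF-β, squares SB431542) against the time in the sample titles, for the 3 cell lines; lines join group means of 3 replicates. In M2 both arms are lowest at 24 h, with means of 9080 after TGF-β and 9310 after SB.

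Because a few genes hold so much of each library, every comparison is given on TPM as deposited and again after rescaling each library by its median ratio to the others (median-of-ratios). As deposited, the median log2 change of all tested genes between 0 h and 24 h of TGF-β was −0.25 in M1, −0.74 in M2 and −0.25 in MDA-MB-231. After rescaling these medians were 0, −0.15 and −0.03. With the 10 most abundant genes left out of the scaling total, a setting chosen after the data were seen, they were −0.10, −0.56 and −0.35. Fold changes are on the log2(TPM + 0.5) scale, which understates the change of genes at low levels. The files do not pair the gene identifiers with names, so 2 genes that rose and 2 that fell are followed by identifier through all comparisons. They are the leading members, in each direction, of the genes called in all 3 lines.

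The first comparison asked whether the arms started from the same state. In M1 and MDA-MB-231 limma called 0 lncRNA genes between the non-stimulated controls and the earliest SB samples, among 20899 and 16552 tested. At an unadjusted p under 0.05 there were 1187 genes in M1 and 839 in MDA-MB-231, and 1222 and 738 after rescaling, which also gave 0 calls. In M2 limma called 2 of 16958 genes, both higher in the controls, and 0 after rescaling. There 1618 genes had an unadjusted p under 0.05 as deposited and 1803 after rescaling, more than in M1, where more genes were tested. The few calls thus do not show that the M2 arms started alike. Their ratio of low to mid-level genes, described below, differed without overlap. The M2 count was 4, 0 or 0 without earliest SB replicate 1, 2 or 3, and 1, 0 or 17 without 0 h replicate 1, 2 or 3. It was 1 in M1 without 0 h replicate 1 or 3, and 1 in MDA-MB-231 without earliest SB replicate 1 or 2. None of the 4 followed genes passed the test in any line. NONHSAG048398.2, the leading gene of the rise described next, stood at 106 ± 11 TPM in the M1 controls and at 97.3 ± 6.51 TPM in the earliest SB samples of M1 (SD, n = 3 each).

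The change with TGF-β was followed against 0 h within each line. These comparisons have no time-matched control, so they also hold other changes over time. NONHSAG048398.2 rose in all 3 lines within 2 h. In M1 it went from 106 ± 11 TPM at 0 h to 490 ± 10.4 at 2 h, 560 ± 28.2 at 8 h and 448 ± 31.3 at 24 h (SD, n = 3). In M2 it went from 12.6 ± 3.36 TPM to 220 ± 40.4, 464 ± 111 and 1828 ± 263 at the same times. In MDA-MB-231 it went from 44.8 ± 7.62 TPM to 274 ± 60.1, 221 ± 15.6 and 169 ± 35.3. The log2 change at 2 h was 2.2 (SE 0.09) in M1, 4.09 (SE 0.29) in M2 and 2.59 (SE 0.20) in MDA-MB-231, with limma adjusted p of 3.89e-13, 1.16e-08 and 1.66e-08. NONHSAG026213.2 also rose by 2 h, to 5.59 ± 1.87 TPM from 1.61 ± 0.538 in M1 (limma adjusted p 0.0354) and to 1.58 ± 0.824 TPM in M2 (adjusted p 0.00276), where the 3 control libraries were listed at 0.43, 0 and 0 TPM. In MDA-MB-231 it was listed at 0 in all 3 control libraries and stood at 2.22 ± 0.253 TPM at 2 h. Neither NONHSAG037983.2 nor NONHSAG003853.2, the genes that later fell, passed the test at 2 h in any line.

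At 2 h limma called 176 lncRNA genes in M1 (105 higher and 71 lower), 119 in M2 (81 and 38) and 96 in MDA-MB-231 (61 and 35). After rescaling the counts were 262 (174 and 88), 229 (166 and 63) and 326 (213 and 113). The M2 count was 37 with the 10 most abundant genes left out of the scaling total, and that of MDA-MB-231 was 165, 67 higher and 98 lower. In M1 the largest rise by the naming rule took a gene from 0.557 ± 0.243 to 11.9 ± 8.55 TPM, and in MDA-MB-231 from 4.0 ± 1.89 to 103 ± 21.9 TPM (n = 3 each); in M2 it was that of NONHSAG048398.2. The 2 h counts depended on single libraries. In M1 the count was 85 or 116 without 0 h replicate 2 or 1, and 112 or 111 without 2 h replicate 1 or 3. In M2 it was 53 without 0 h replicate 2, and 62 or 64 without 2 h replicate 1 or 2. In MDA-MB-231 it was 63 or 153 without 0 h replicate 1 or 3, and 60, 54 or 57 without 2 h replicate 1, 2 or 3.

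At 8 h NONHSAG026213.2 had risen to 14.3 ± 2.03 TPM in M1 and 6.40 ± 0.32 TPM in M2, and stood at 2.09 ± 0.46 TPM in MDA-MB-231 (SD, n = 3). Both falling genes had fallen in M1 by then, NONHSAG037983.2 from 24.0 ± 5.80 to 9.50 ± 1.01 TPM and NONHSAG003853.2 from 130 ± 7.71 to 31.7 ± 4.96 TPM. Their limma adjusted p in M1 were 6.67e-05 and 1.31e-05. NONHSAG003853.2 had also fallen under SB in M1 at 8 h (log2 change −1.345, limma adjusted p 0.00264). It did not differ there between TGF-β and SB (−0.32, adjusted p 0.536), while NONHSAG037983.2 was lower with TGF-β (−0.80, adjusted p 0.00581). Against 0 h the limma adjusted p of NONHSAG037983.2 and NONHSAG003853.2 were 0.438 and 0.641 in M2, and 0.303 and 0.564 in MDA-MB-231. Limma called 1902 lncRNA genes at 8 h in M1 (1103 higher, 799 lower), 824 in M2 (450 and 374) and 211 in MDA-MB-231 (97 and 114). After rescaling there were 2241 in M1 (1088 higher, 1153 lower), 1490 in M2 (891 and 599) and 556 in MDA-MB-231 (315 and 241). With the 10 most abundant genes left out of the scaling total the M2 count was 404 (322 higher, 82 lower), and without 27 variable abundant genes, also chosen after the data were seen, it was 1369 (476 and 893). The M2 count was 545 without 0 h replicate 1 and 498 without 8 h replicate 2. The MDA-MB-231 count was 116 or 115 without 0 h replicate 1 or 2, and 113 or 136 without 8 h replicate 2 or 3.

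**Figure D2:**
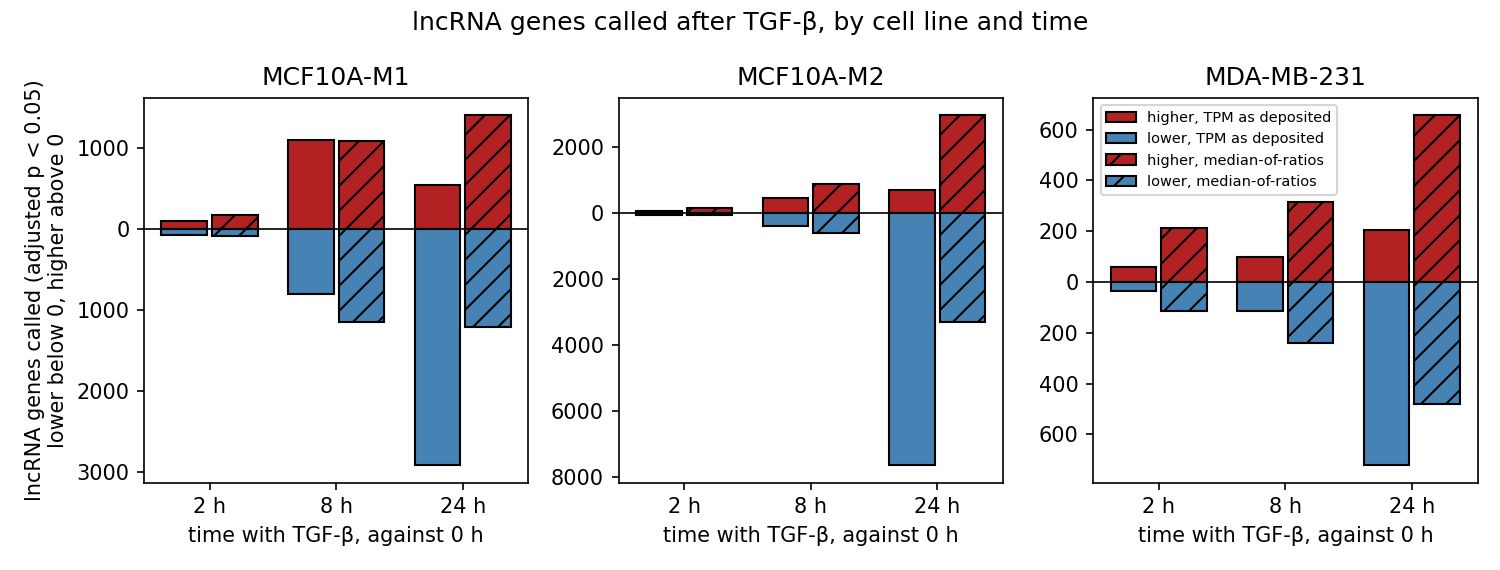
Number of lncRNA genes called by limma (adjusted p under 0.05) at 2, 8 and 24 h of TGF-β against 0 h in each line, higher genes above 0 and lower genes below, from TPM as deposited (plain bars) and after median-of-ratios rescaling (hatched bars); the vertical scales differ between lines. At 24 h most calls are lower as deposited in all 3 lines (2917 of 3461 in M1), while after rescaling both directions are of similar number (1407 higher and 1207 lower in M1).

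At 24 h the counts were largest in every line. In M1 limma called 3461 of 20899 genes, 544 higher and 2917 lower; after rescaling it called 2614, 1407 higher and 1207 lower. The 544 higher genes were called higher under both scalings, and 1207 genes were called lower under both. NONHSAG037983.2 fell from 24.0 ± 5.80 to 2.77 ± 0.777 TPM and NONHSAG003853.2 from 130 ± 7.71 to 15.8 ± 9.50 TPM (SD, n = 3). Their log2 changes were −2.91 (SE 0.18) and −3.15 (SE 0.25) as deposited and −2.56 and −2.77 after rescaling. NONHSAG048398.2 changed by 2.07 (SE 0.09) and NONHSAG026213.2 by 2.64 (SE 0.35), with limma adjusted p of 3.48e-13 and 9.86e-06.

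In M2 limma called 8365 of 16958 genes at 24 h, 714 higher and 7651 lower; after rescaling it called 6266, 2971 higher and 3295 lower. The 714 higher genes were called higher under both scalings and 3295 genes lower under both, while 202 genes were called lower as deposited and higher after rescaling. Leaving the 10 most abundant genes out of the scaling total gave 4648, 1058 higher and 3590 lower. NONHSAG048398.2 changed by 7.15 (SE 0.29, limma adjusted p 1.75e-14) and NONHSAG026213.2 by 4.07 (SE 0.29, adjusted p 1.12e-10), the latter to 9.97 ± 1.98 TPM; after rescaling the changes were 8.24 and 4.84. NONHSAG003853.2 fell from 53.1 ± 4.35 to 3.54 ± 0.474 TPM, and NONHSAG037983.2 from 9.44 ± 3.19 TPM to libraries listed at 0, 0 and 0.505 TPM. Their log2 changes were −3.73 (SE 0.25) and −3.92 (SE 0.34) as deposited, and −2.70 and −3.47 after rescaling. The largest rise by the naming rule took a gene from 0.635 ± 0.299 to 549 ± 36.8 TPM (n = 3 each). The largest fall was from 11390 ± 18900 to 10.6 ± 3.99 TPM (limma adjusted p 0.0172), with a wide spread between the 0 h libraries. It was not called after rescaling (limma adjusted p 0.0533).

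In MDA-MB-231 limma called 924 of 16552 genes at 24 h, 203 higher and 721 lower; after rescaling it called 1138, 656 higher and 482 lower. The 203 higher genes were called higher under both scalings, and 465 genes lower under both. NONHSAG026213.2 stood at 1.79 ± 0.0346 TPM, against 0 in all 3 controls, and NONHSAG048398.2 changed by 1.89 (SE 0.20, limma adjusted p 3.3e-06). NONHSAG037983.2 fell from 3.52 ± 0.782 to 1.02 ± 0.624 TPM (log2 change −1.47, SE 0.29, adjusted p 0.00254). NONHSAG003853.2 went from 31.0 ± 6.19 to 15.8 ± 4.39 TPM (log2 change −0.97, SE 0.28, adjusted p 0.0375), a limma call that was lost without 0 h replicate 1 or 2 (adjusted p 0.0741 and 0.168) and without 24 h replicate 2 or 3 (adjusted p 0.222 and 0.0536). The call was also lost with no filter, with only the compared groups in the fit, and without the variable abundant genes. The MDA-MB-231 count was 486 or 423 without 0 h replicate 1 or 2, and 422 or 578 without 24 h replicate 2 or 3.

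The lines were then compared for genes that changed in common over 24 h of TGF-β. Without a time-matched control, these genes may also hold other changes over 24 h. Of 13631 lncRNA genes tested in every line, 31 were called higher and 216 lower in all 3 lines at 24 h of TGF-β. Independent lists would share 0.12 higher and 60.3 lower genes. After rescaling 128 were higher and 70 lower, against 7.43 and 6.53 for independent lists. The 31 higher genes were shared under both scalings, as were 69 of the lower genes. Rescaling shifted the 24 h changes upward in every line, and every gene called higher as deposited stayed called higher. That the 31 genes stayed shared is therefore no separate support for them. NONHSAG048398.2 and NONHSAG026213.2 ranked highest among the shared risen genes by mean log2 change, and NONHSAG037983.2 and NONHSAG003853.2 among the shared fallen genes; all 4 were shared under both scalings. Across genes the 24 h log2 changes correlated with r = 0.469 between M1 and M2, 0.273 between M2 and MDA-MB-231 and 0.162 between M1 and MDA-MB-231; genes are not independent replicates. The 247 shared genes became 137 or 126 without MDA-MB-231 0 h replicate 1 or 2, and 114 without MDA-MB-231 24 h replicate 2.

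**Figure D3:**
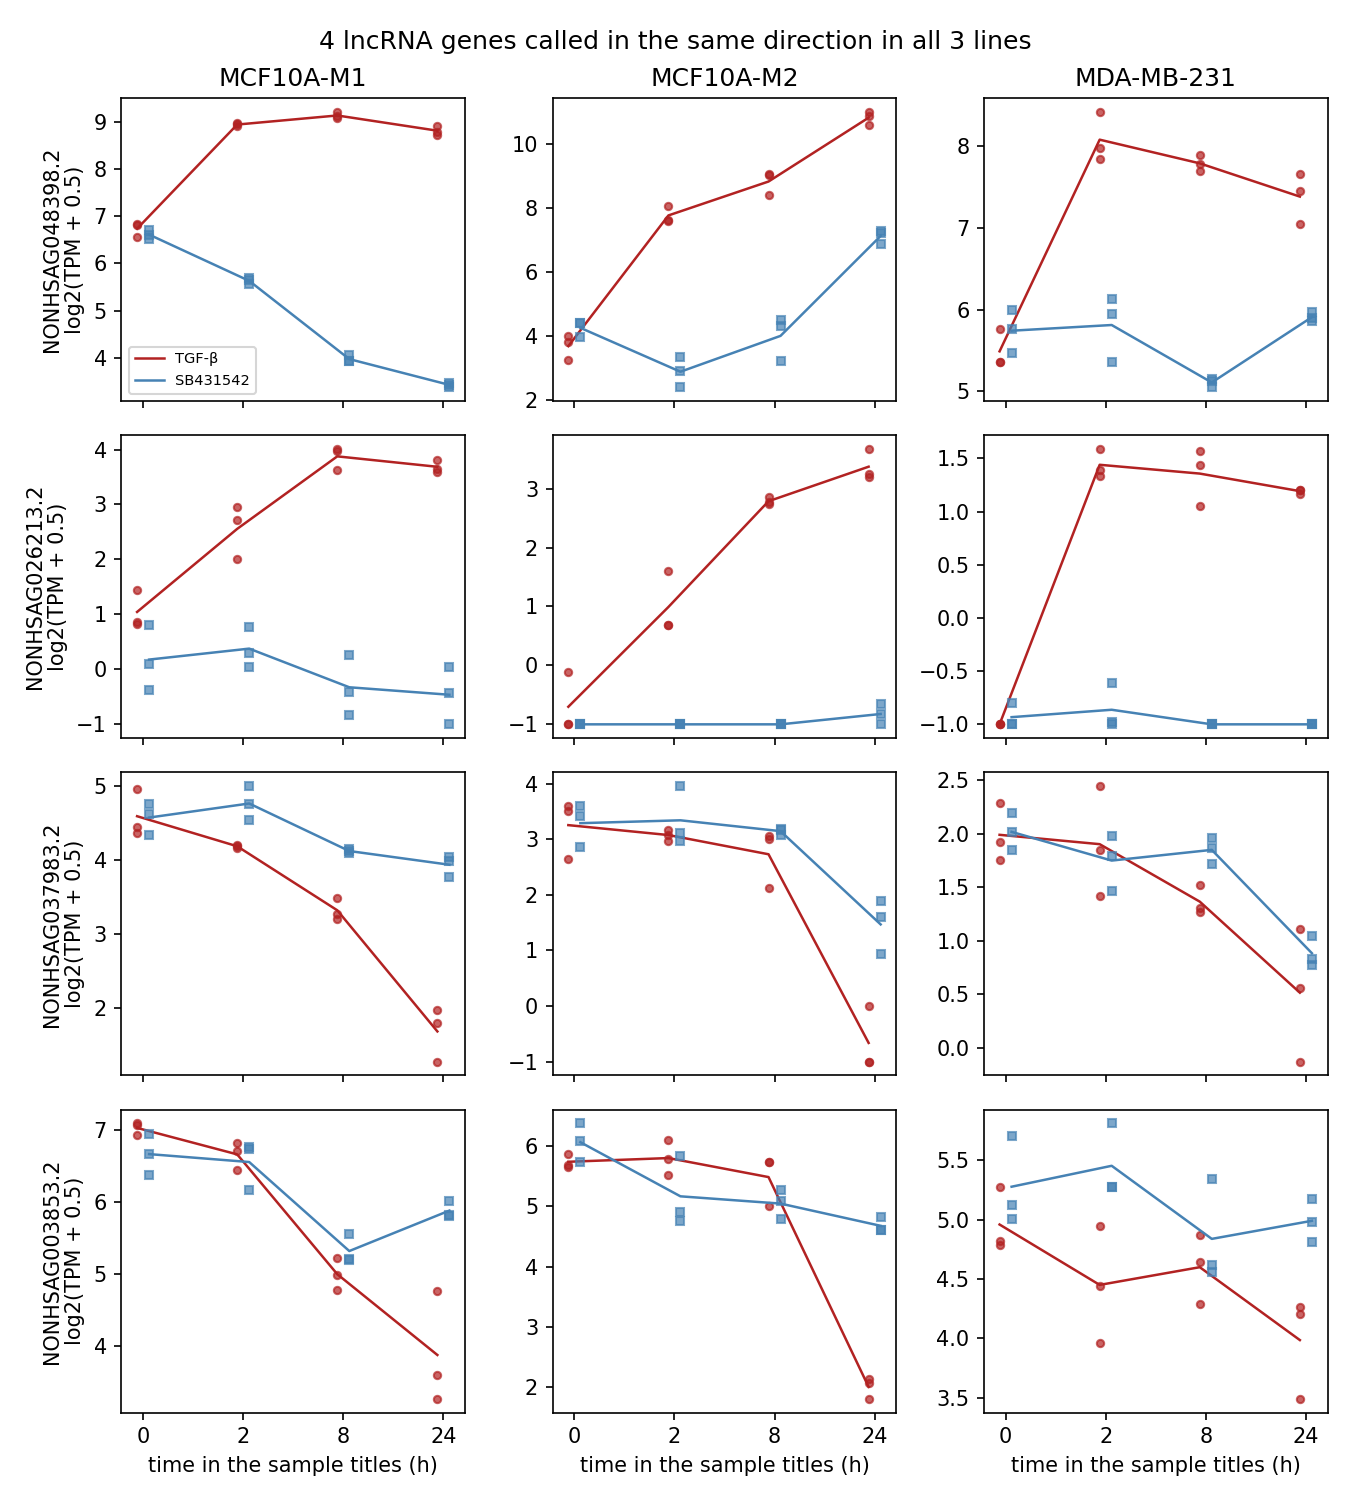
Level of 4 lncRNA genes (rows), as log2(TPM + 0.5), against the time in the sample titles (not to scale) in the 3 cell lines (columns); points are the 3 replicates (circles TGF-β, squares SB431542), lines join their means, and each panel has its own vertical range. NONHSAG048398.2 stands at 10.3 TPM in M1 after 24 h of SB and at 448 TPM after 24 h of TGF-β; the lower 2 rows show the genes that fell after TGF-β in every line.

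The ligand and the receptor inhibitor were compared at 24 h. NONHSAG048398.2 was higher with TGF-β than with SB in each line, by 5.38 (SE 0.09) in M1, 3.70 (SE 0.29) in M2 and 1.48 (SE 0.20) in MDA-MB-231 on the log2 scale, with limma adjusted p of 1.9e-21, 2.46e-09 and 7.29e-05. NONHSAG026213.2 was higher by 4.15 (SE 0.35) in M1 and 4.20 (SE 0.29) in M2 (4.42 and 4.85 after rescaling), and was listed at 0 in all 3 SB libraries of MDA-MB-231 at 24 h. NONHSAG037983.2 was lower with TGF-β by a log2 difference of −2.25 (SE 0.18) in M1 and −2.13 (SE 0.34) in M2. Its difference of −0.37 (SE 0.29) in MDA-MB-231 did not pass the test (limma adjusted p 0.435). NONHSAG003853.2 was lower in M1 (−2.0, SE 0.25) and M2 (−2.67, SE 0.25); its difference in MDA-MB-231 (−1.0, SE 0.28, limma adjusted p 0.0379) did not pass after rescaling (−0.54, adjusted p 0.0909). That call was also lost under the other scalings tried, with no filter and without the variable abundant genes. The adjusted p was 0.15, 0.0612 and 0.0828 without SB replicate 1, 2 and 3, and 0.247 and 0.0554 without TGF-β replicate 2 and 3.

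Limma called 3044 genes between TGF-β and SB at 24 h in M1 (874 higher with TGF-β, 2170 lower), 1811 in M2 (531 and 1280) and 726 in MDA-MB-231 (107 and 619). After rescaling there were 2773 in M1 (1588 higher, 1185 lower), 3059 in M2 (1621 and 1438) and 513 in MDA-MB-231 (324 and 189). There were 1268 in M2 (622 and 646) and 373 in MDA-MB-231 (102 and 271) with the 10 most abundant genes left out of the scaling total. The median log2 difference of all tested genes was −0.21, −0.09 and −0.33 as deposited. Called under both scalings were 874 higher and 1181 lower genes in M1, 531 and 1175 in M2, and 107 and 189 in MDA-MB-231. The MDA-MB-231 count was 259, 422 or 394 without SB replicate 1, 2 or 3, and 201 or 418 without TGF-β replicate 2 or 3.

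The SB arm was followed from its earliest samples to 24 h. In M1 NONHSAG048398.2 fell from 97.3 ± 6.51 to 10.3 ± 0.331 TPM (log2 change −3.18, SE 0.09, limma adjusted p 1.58e-16; n = 3 libraries per group). In M2 it rose under SB too, from 18.8 ± 3.23 to 140 ± 20.2 TPM (log2 change 2.87, SE 0.29, limma adjusted p 2.02e-07; 3.77 after rescaling). In MDA-MB-231 it was 53.6 ± 9.72 TPM and then 59.5 ± 2.36 TPM (limma adjusted p 0.767). NONHSAG037983.2 fell under SB in all 3 lines, with log2 changes of −0.64 (SE 0.18) in M1, −1.82 (SE 0.34) in M2 and −1.13 (SE 0.29) in MDA-MB-231 and limma adjusted p of 0.0413, 0.000326 and 0.0381; after rescaling the changes were −0.64, −1.0 and −1.07 and passed as well. NONHSAG003853.2 fell in M2 by 1.39 on the log2 scale (SE 0.25), and its change after rescaling was −0.48 (limma adjusted p 0.0119). In M1 its change of −0.78 passed only after rescaling (adjusted p 0.0802 as deposited and 0.0202 rescaled). NONHSAG026213.2 did not pass the test in any line.

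Limma called 1097 genes over the SB course in M1 (420 higher, 677 lower), 6304 in M2 (341 and 5963) and 314 in MDA-MB-231 (146 and 168). After rescaling it called 1414 in M1 (563 and 851), 3492 in M2 (1838 and 1654) and 721 in MDA-MB-231 (400 and 321). Leaving the 10 most abundant genes out of the scaling total gave 1421 in M1 (776 and 645), 1495 in M2 (448 and 1047) and 201 in MDA-MB-231 (106 and 95). In M2 the median log2 change of all tested genes was −0.63 as deposited and −0.11 after rescaling. The M1 count was 700, 707 or 719 without 24 h replicate 1, 2 or 3, and the M2 count 4034 without earliest SB replicate 3. The MDA-MB-231 count was 170, 134 or 143 without earliest SB replicate 1, 2 or 3, and 110 or 106 without 24 h replicate 1 or 2.

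The lines also differed before stimulation. All 4 followed genes were lower in the non-stimulated M2 and MDA-MB-231 cells than in M1, under both scalings. NONHSAG048398.2 was lower by a log2 difference of −3.05 (SE 0.22) in M2 and −1.25 (SE 0.16) in MDA-MB-231, and of −2.62 and −0.52 after rescaling. NONHSAG037983.2 differed by −1.33 (SE 0.28) and −2.60 (SE 0.23), and NONHSAG003853.2 by −1.29 (SE 0.26) and −2.07 (SE 0.28); after rescaling these were −0.91 and −1.91, and −0.85 and −1.35. The largest difference by the naming rule between MDA-MB-231 and M1 was that of a gene at 6840 ± 661 TPM in M1 and 0.162 ± 0.0792 TPM in MDA-MB-231, and between M2 and M1 that of a gene at 193 ± 56.8 TPM in M1 and 1.74 ± 1.35 TPM in M2 (n = 3 each).

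Limma called 4209 of 21857 genes between M2 and M1 (464 higher in M2, 3745 lower) and 11027 of 22921 between MDA-MB-231 and M1 (2207 higher in MDA-MB-231, 8820 lower). After rescaling it called 2951 (1367 higher, 1584 lower) and 9767 (4275 higher, 5492 lower). The median log2 difference of all tested genes was −0.34 for M2 and −0.47 for MDA-MB-231 as deposited. The M2 count was 2422 without M2 0 h replicate 2, a library in which 4 co-varying genes took 23.9% of the TPM.

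Whether the change from 0 h to 24 h of TGF-β differed between lines was tested as an interaction. It has no time-matched control, so it also holds other changes over 24 h. The rise of NONHSAG048398.2 was larger in M2 than in M1 by 5.07 on the log2 scale (SE 0.32, limma adjusted p 5.46e-15) and by 5.89 after rescaling. For MDA-MB-231 against M1 the difference was −0.18 (SE 0.22, adjusted p 0.757). Over the SB course, however, NONHSAG048398.2 rose in M2 (2.87) and fell in M1 (−3.18). Between TGF-β and SB at 24 h its difference was larger in M1 (5.38) than in M2 (3.70). NONHSAG026213.2 rose more in M2 than in M1 by 1.43 (SE 0.44, limma adjusted p 0.023) and by 2.31 after rescaling. It started lower in M2, with controls listed at 0.43, 0 and 0 TPM, against 1.61 ± 0.538 TPM in M1. At 24 h it stood at 9.97 ± 1.98 TPM in M2 and 12.4 ± 0.99 TPM in M1. Between TGF-β and SB at 24 h its difference was 4.20 in M2 and 4.15 in M1 (4.85 and 4.42 after rescaling). The difference for NONHSAG037983.2 between M2 and M1 was −1.01 (limma adjusted p 0.0862), and passed only after rescaling (−1.17, adjusted p 0.023). The fall of NONHSAG003853.2 was smaller in MDA-MB-231 than in M1, by 2.18 (SE 0.39, limma adjusted p 0.000437), and so was that of NONHSAG037983.2, by 1.44 (SE 0.33, adjusted p 0.0063). Limma called 2969 of 21857 genes for M2 against M1, of which 446 changed more positively and 2523 more negatively in M2; after rescaling it called 3539 (2053 and 1486). For MDA-MB-231 against M1 it called 1004 of 22921 genes (574 and 430), and 1754 (926 and 828) after rescaling. With the 10 most abundant genes left out of the scaling total the counts were 1760 (499 and 1261) for M2 and 1204 (318 and 886) for MDA-MB-231. The median log2 difference in response of all tested genes was −0.37 for M2 and 0.04 for MDA-MB-231 as deposited.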

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

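The tests of the M2 fall and of the co-varying genes and the breakdown of the regroupings were chosen after the results were seen; the regroupings followed a rule set beforehand, but what they would show was written down after they were run.

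By the interaction test the change from 0 h to 24 h of TGF-β differed for 2969 lncRNA genes in M2 against M1. For MDA-MB-231 against M1 it differed for 1004. The test has no time-matched control, so it cannot separate the response to the ligand from other changes over 24 h. M2 also changed broadly under SB, with 6304 genes called over the SB course, 5963 of them lower, against 1097 called in M1. In M2 4496 genes were called lower and 197 higher in both arms, as deposited. The direction depended on the scaling. After median-of-ratios scaling 3492 genes were called over the SB course of M2 (1838 higher, 1654 lower). In both arms 1320 were then higher and 1037 lower. Among genes called in both lines and in the interaction, 44 rose in M1 and fell in M2 and 23 did the opposite (55 and 81 after median-of-ratios scaling). For MDA-MB-231 against M1 these numbers were 15 and 16 (24 and 33 after scaling). In 10 of 100 regroupings of the times within the lines, the real one included, at least 2969 genes were called for M2, and the highest other count was 7835. For MDA-MB-231 it was 6 of 100, with a highest other count of 4000. These regroupings do not exclude chance, and they cannot decide the question. Those that leave the real times of a line whole or exactly reversed keep that line's whole change over 24 h. Their counts, with 7835 and 4000 among them, therefore hold that change. Each of the 9 other regroupings as large for M2, and each of the 5 for MDA-MB-231, left the real times of a line whole or exactly reversed. In all, 18 other regroupings for M2 and 21 for MDA-MB-231 did so, of which 9 and 5 were as large. The 81 and 78 regroupings that did not leave a line so reached at most 456 and 12 genes. They mix 0 h and 24 h libraries within groups, so the real change of each line widens the spread and lowers their counts. Their low counts are therefore no measure of chance calls either.

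The SB libraries at 2 and 8 h entered the fits of their lines, and were not compared with the earliest SB samples in the report. Against the earliest SB samples limma called 17 lncRNA genes at 2 h and 770 at 8 h in M1, 507 and 340 in M2, and 40 at 8 h in MDA-MB-231, more than the 0, 2 and 0 called between the starting samples of the arms. At 2 h in MDA-MB-231 limma called 0 genes under both scalings, with 1007 at an unadjusted p under 0.05 as deposited and 1101 after rescaling. At 2 h there were 6 higher and 11 lower in M1, and 2 higher and 505 lower in M2; after median-of-ratios scaling there were 7 and 21, and 0 and 1. At 8 h there were 391 higher and 379 lower in M1, 22 and 318 in M2 and 3 and 37 in MDA-MB-231; after scaling these were 421 and 701, 196 and 104, and 41 and 27, so the majority turned in M2 and MDA-MB-231.

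In TPM as deposited, most of the lncRNA genes called in M2 at 24 h were lower than at the start with TGF-β and with SB, while after median-of-ratios scaling 2971 were higher and 3295 lower with TGF-β, and 1838 and 1654 with SB. With the 10 most abundant genes left out of the scaling total, the median log2 change of all tested genes was still −0.562 with TGF-β and −0.36 with SB, against 0.14 between the starting samples of the arms, which argues against a scale factor from those 10 genes as the whole cause. Any single factor per library would leave unchanged the ratio between the summed TPM of low genes (mean under 2 TPM, 10394 genes) and mid-level genes (10 to 1000 TPM, 3103 genes). Under SB this ratio fell to 0.649 of its start. Every SB library at 24 h (0.0218 to 0.0252) lay below the starting libraries of both arms (0.0458 to 0.0557 at 0 h, 0.032 to 0.0429 in the earliest SB samples). The same held when the median of the mid-level genes replaced their sum. These values argue against a single factor as the whole cause in the SB arm. No ligand was added there, so they also argue against the added ligand as the whole cause of the falls in both arms. What part the ligand had in the fall with TGF-β cannot be told, because SB is itself a treatment and has no time-matched control. Signalling that escaped the inhibitor stays open as well. With TGF-β the ratio fell to 0.567 of its start, but a single factor cannot be told apart there, because the starting libraries of the arms already differed without overlap and the libraries at 24 h (0.0243 to 0.0335) overlapped the earliest SB samples; with TGF-β and SB it was 0.997 and 1.12 of its start in M1 and 0.82 and 0.933 in MDA-MB-231, without overlap for SB in both lines. Lower sequencing depth at 24 h cannot be told apart either, in either arm. With TGF-β the number of genes above 0 was 96.9% of that at 0 h, while the 0 h libraries alone spread from 18791 to 22653. Under SB that number was 20767 ± 631 in the earliest samples and 19128 ± 892 at 24 h (SD, n = 3). Every SB library at 24 h (18413 to 20127) lay below every earliest SB library (20141 to 21403). Time without serum, unspliced RNA and genomic DNA were not tested.

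A group of 4 abundant lncRNA genes with consecutive identifiers rose and fell together between replicates (correlation of their deviations from the group means at least 0.9998) and took from 0.00489% to 23.9% of a library. The highest share was in M2 TGF-β 0 h replicate 2, followed by 7.66% in M2 TGF-β 2 h replicate 1 and 5.31% in M2 SB 0 h replicate 3. Permuting the treatment groups within lines gave p = 0.415 (permutation test, 100000 resamples), so this test detected no link to the groups and did not exclude one. In M2 the share was 0.376%, 23.9% and 0.313% at 0 h, and 0.0111%, 0.00528% and 0.00904% after 24 h of TGF-β. As deposited, the largest falls by the naming rule in that comparison were of genes in this group (limma adjusted p 0.0166 to 0.0172). After rescaling they were not called (limma adjusted p 0.0533 to 0.0537). Uneven removal of an abundant RNA is a candidate explanation that was not tested, since the genes could not be named here. Leaving these and the other variable abundant genes out moved the M2 8 h count from 824 to 1369 and the MDA-MB-231 count against SB at 24 h from 726 to 480.

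For each comparison of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real split ranked first (1 of 10) in 17 of these 20 comparisons. Every other split mixes libraries of the real groups on each side. A real difference then widens the spread within groups and lowers the other counts, so they do not measure chance calls. Over the TGF-β course the highest other counts at 2, 8 and 24 h were 2, 3 and 1 in M1 (real 176, 1902 and 3461), 29, 3 and 0 in M2 (119, 824 and 8365) and 1, 2 and 1 in MDA-MB-231 (96, 211 and 924). Between TGF-β and SB at 24 h the highest other count was 1 in each line (real 3044, 1811 and 726). Over the SB course the highest other counts were 1, 0 and 0 (real 1097, 6304 and 314). Against M1 they were 13 for M2 (real 4209) and 4 for MDA-MB-231 (real 11027). Between the starting samples all 10 splits were as large in M1 and MDA-MB-231 (real 0, highest other 1), and 3 of 10 in M2 (real 2, highest other 24). Of 100 regroupings for the genes shared by the lines, 1, the real one with 247 genes, was that large, and the highest other count was 0. Regrouping takes away the calls within each line as well, so this does not test whether the sharing between lines exceeds chance.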

How the results depend on the processing

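Leaving out the variable abundant genes, leaving the 10 most abundant genes out of the scaling total, and quantile normalization were chosen after the data were seen. Counts are lncRNA genes called, and a count within 1.5 times the reported one is taken as unmoved. The causes of the moves were not tested. Leaving out libraries, or fitting only the compared groups, leaves fewer samples to estimate the spread. Fitting only the compared groups also changes which genes are tested. For TGF-β against SB in M2 it tested 9335 genes instead of 16958, and the count rose from 1811 to 2805.

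With median-of-ratios scaling 9 of 23 counts moved: M2 at 2 h to 229 and at 8 h to 1490, MDA-MB-231 at 2 h to 326 and at 8 h to 556, M2 TGF-β against SB to 3059, the SB course to 3492 in M2 and 721 in MDA-MB-231, the M2 starting samples to 0, and the interaction of MDA-MB-231 with M1 to 1754. The majority of calls turned from lower to higher in MDA-MB-231 at 8 h, in M1 and MDA-MB-231 at 24 h, for TGF-β against SB in each line, in the SB course of M2 and MDA-MB-231, in the interaction of M2 with M1 and for the shared genes, and from higher to lower in M1 at 8 h. In the other comparisons with calls under both scalings it stayed.

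Fitting only the groups compared moved 14 counts: M1 at 2 h to 43 and at 24 h to 2254, M2 at 2 h to 41 and at 8 h to 411, MDA-MB-231 at 2, 8 and 24 h to 48, 83 and 358, TGF-β against SB to 2805 in M2 and 460 in MDA-MB-231, the starting samples to 0 in M2 and 1 in MDA-MB-231, M2 against M1 to 2483, the interaction of MDA-MB-231 to 351, and the genes shared by the lines to 99.

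The pseudocount of 0.1 moved M2 at 2 h to 75 and the M2 starting samples to 1; the pseudocount of 1 moved the starting samples to 1 in M1 and 8 in M2. Without a filter the starting samples gave 2, 24 and 3 genes in M1, M2 and MDA-MB-231. The stricter filter, which tests fewer genes, gave 71 for M2 at 2 h, 0 for the M2 starting samples and 7325 for MDA-MB-231 against M1. Without the 27 variable abundant genes M2 at 8 h gave 1369, TGF-β against SB in MDA-MB-231 480 and the M2 starting samples 6. Higher and lower calls there were 88 and 64 in M2 at 2 h (81 and 38 as reported), 476 and 893 at 8 h (450 and 374), 238 and 504 in MDA-MB-231 at 24 h (203 and 721), and 774 and 377 in its interaction with M1 (574 and 430).

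With the 10 most abundant genes left out of the scaling total, 9 counts moved: M2 at 2, 8 and 24 h to 37, 404 and 4648, MDA-MB-231 at 2 h to 165, TGF-β against SB in MDA-MB-231 to 373, the SB course to 1495 in M2 and 201 in MDA-MB-231, the M2 starting samples to 0, and the interaction of M2 with M1 to 1760. Among counts that did not move, the balance shifted in M1 at 8 h (1019 higher and 1063 lower, against 1103 and 799) and at 24 h (1023 higher and 1675 lower, against 544 and 2917), MDA-MB-231 at 8 h (91 and 169, against 97 and 114), TGF-β against SB in M1 (1168 and 1862, against 874 and 2170) and M2 (622 and 646, against 531 and 1280), the SB course of M1 (776 and 645, against 420 and 677), MDA-MB-231 against M1 (3626 and 5902, against 2207 and 8820) and their interaction (318 and 886, against 574 and 430). In M2 at 2 h it was 29 and 8, against 81 and 38.

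Quantile normalization moved 10 counts: M2 at 2, 8 and 24 h to 236, 1713 and 5567, MDA-MB-231 at 2 and 8 h to 216 and 524, TGF-β against SB in M2 to 2888, the SB course to 3042 in M2 and 825 in MDA-MB-231, the M2 starting samples to 0, and the interaction of MDA-MB-231 with M1 to 1769. Calls at 2 h stayed mostly higher (175 and 87 in M1, 165 and 71 in M2, 158 and 58 in MDA-MB-231). At 24 h against 0 h there were 1327 higher and 1286 lower in M1 (544 and 2917 as reported), 2796 and 2771 in M2 (714 and 7651) and 640 and 524 in MDA-MB-231 (203 and 721). Against SB there were 1477 and 1400 in M1 (874 and 2170), 1426 and 1462 in M2 (531 and 1280) and 313 and 202 in MDA-MB-231 (107 and 619). The SB course of M2 gave 1514 and 1528 (341 and 5963). M2 against M1 gave 1392 and 1506 (464 and 3745), MDA-MB-231 against M1 4875 and 4761 (2207 and 8820), and the interaction of M2 with M1 1335 and 1350 (446 and 2523).

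The replicate numbers showed little sign of pairing the samples, although pairing for some genes or groups was not excluded. The deviations of same-numbered libraries correlated on average by 0.00058 in M1, −0.0072 in M2 and 0.0025 in MDA-MB-231. Only 6 and 7 of 84 pairs in M2 and MDA-MB-231, and 0 in M1, were over 0.1. The pairs ranged from −0.144 to 0.139 in M2 and from −0.112 to 0.141 in MDA-MB-231. With the replicate block the M2 starting samples gave 1 gene, and the other 22 counts stayed within 1.5 times. Lower calls alone moved further in MDA-MB-231, at 2 h to 65 (with 65 higher, against 61 higher and 35 lower), at 8 h to 183 from 114 and against SB at 24 h to 943 from 619.

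With each library left out in turn, some of the counts moved. The ranges given for them here hold all libraries left out, whether or not the count moved. They were 85 to 120 in M1 at 2 h, 53 to 113 in M2 at 2 h and 498 to 703 in M2 at 8 h. In MDA-MB-231 they were 54 to 153, 113 to 305, and 422 to 1351 at 2, 8 and 24 h. TGF-β against SB in MDA-MB-231 gave 201 to 920. The SB course gave 700 to 761 in M1, 4034 to 6263 in M2 and 106 to 351 in MDA-MB-231. The starting samples gave 0 to 1 in M1, 0 to 17 in M2 and 0 to 1 in MDA-MB-231; M2 against M1 gave 2422 to 4152, and the shared genes 114 to 330. The other counts stayed within 1.5 times.

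None of the 4 followed genes changed direction at 24 h, against 0 h or SB, under any of these alternatives. NONHSAG003853.2 in MDA-MB-231 was the only one to lose a call: against 0 h with no filter, with only the compared groups and without the variable genes, and against SB with no filter, with each of the other scalings (−0.54 with median-of-ratios, −0.90 without the 10 most abundant genes in the total, −0.54 with quantile normalization) and without the variable genes; the report gives the libraries on which these calls rested. In MDA-MB-231 NONHSAG026213.2 was below the stricter filter and has no value there. The gene list tests and their alternatives (an estimated correlation, a replicate block) were not run, since the identifiers carry no names. Depth is unknown, so how far it limits the low genes cannot be stated.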

Other observations

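The tests in this part were chosen after the genes shared by the lines were seen, and the limit that decides the test of the shared genes was changed after its result was seen.

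TGF-β and SB were also compared at 2 and 8 h, where no library is shared with the comparison at 24 h. The lists of a line still come from the same fit and share its filter, scaling and estimate of each gene's spread. A gene with a small estimated spread is more easily called in both lists. The numbers for independent lists are therefore only a reference, and an excess over them does not by itself show a common effect. In M1, limma called 215 lncRNA genes higher with TGF-β than with SB at 2 h and 874 at 24 h, and 148 were called at both times, against 8.99 for independent lists. In M2 these numbers were 684, 531 and 166 (21.4 for independent lists), and in MDA-MB-231 81, 107 and 43 (0.524). After median-of-ratios scaling 278, 314 and 263 genes were higher at 2 h and 1588, 1621 and 324 at 24 h, and 213, 194 and 105 at both, against 21.1, 30.0 and 5.15. The genes lower with TGF-β at 2 h were 67 in M1, 18 in M2 and 108 in MDA-MB-231, of which 43, 7 and 29 were lower at 24 h too (6.96, 1.36 and 4.04 for independent lists). After scaling they were 93, 88 and 237, with 52, 34 and 26 lower at both times (5.27, 7.46 and 2.71). NONHSAG048398.2 was among the genes higher with TGF-β at each time in each line, with log2 differences from SB at 2 h of 3.31 in M1, 4.89 in M2 and 2.27 in MDA-MB-231. NONHSAG026213.2 was higher at 2 h by 2.18 in M1, and was listed at 0 in all 3 SB libraries of M2 at 2 h. Of the falling genes, NONHSAG037983.2 passed the test only in M1 at 8 h (−0.80, limma adjusted p 0.00581). NONHSAG003853.2 passed at neither 2 nor 8 h in any line. Its differences at 8 h were −0.32 in M1, 0.44 in M2 and −0.24 in MDA-MB-231.

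The change over 24 h of TGF-β and that over 24 h of SB were set side by side, with no library in common. Here too both lists of a line share the filter, scaling and spread of the same fit. The numbers for independent lists are again only a reference. Across genes their log2 changes correlated with r = 0.13 in M1, 0.565 in M2 and 0.367 in MDA-MB-231 (0.115, 0.546 and 0.383 after median-of-ratios scaling); genes are not independent replicates. In TPM as deposited 197 genes rose and 4496 fell in both arms of M2, against 14.4 and 2690 for independent lists, 65 and 264 in M1 (10.9 and 94.5) and 40 and 91 in MDA-MB-231 (1.79 and 7.32). After the scaling 1320 genes rose and 1037 fell in both arms of M2, against 322 and 321 for independent lists, while 73 rose with TGF-β and fell with SB (290 for independent lists). In MDA-MB-231 171 rose and 111 fell in both arms, against 15.9 and 9.35. In M1 169 rose and 199 fell in both (37.9 and 49.1), and 183 rose with TGF-β and fell with SB (57.3).

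A hypothesis was that the genes called in all 3 lines under both scalings follow TGF-β signalling rather than time in culture. It was tested as the difference between TGF-β and SB at 8 h after median-of-ratios scaling, less the median of all genes. The 8 h libraries were in none of the contrasts that chose the genes, but they entered the same fits and so their filter, spread and scaling. The 31 shared risen genes had median log2 differences of 1.84 in M1, 1.58 in M2 and 1.39 in MDA-MB-231, and 31, 30 and 31 of them were higher with TGF-β. The 69 shared fallen genes had medians of −0.604 in M1 and −0.482 in M2, with 63 and 62 of them lower. In MDA-MB-231 their median was −0.0932 and 41 of 69 were lower, against 50% of all genes. The data are thus consistent with TGF-β signalling for the shared rises in every line and for the shared falls in M1 and M2. For the falls in MDA-MB-231 a first limit, also set after the values were seen, counted a share as low as 41 of 69 against TGF-β signalling. It was then replaced by one that needs most genes to go the other way, under which the 8 h libraries decide nothing, so both TGF-β signalling and time in culture stay open.

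One abundant lncRNA gene ranged from 0.289 to 52200 TPM over the 72 libraries, with a median of 14700. Within one group, M2 after 24 h of SB, it stood at 48900, 0.597 and 52200 TPM in replicates 1, 2 and 3.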
